A study of Oryza sativa with 12 samples.

How the data were processed

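Poly(A) RNA of rice anthers was sequenced from wild-type plants and the nup1 mutant at anther stages 10 and 11, with 3 biological replicates in each of the 4 groups and 12 libraries in all. Libraries were made with the NEBNext Ultra kit and read as pairs of 150 bases on an Illumina NovaSeq platform, per the labels' protocols and the series design text. Per the same text, reads were trimmed and mapped with HISAT2 to release 7 of the MSU rice genome, and expression and differential expression were computed with Cufflinks at a false discovery rate under 0.01 and a fold over 2. The versions of both tools are not given in the sources used here.

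The values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), which the authors deposited in 2 tables, 1 per stage, with 1 column per library and the authors' direction for each gene. Both tables used here hold genes that carry such a direction, so each gene had been selected by the authors for a difference between the genotypes. Counts of genes higher and lower are therefore counts of the authors' calls, and no p-value, q-value or raw count was used. The ratio of mean FPKM was under 2-fold in 209 listed genes at stage 10 and 338 at stage 11. Mean FPKM went against the authors' direction in 7 and 9 genes, and 2 of the genes past the limma threshold at stage 11 did so. A second fit to a selected table cannot test those calls independently. The p-values below set a gene's change against the spread of its replicates, and adjustment runs over listed genes alone. Background genes that did not change are not analysed here, so no enrichment against them was computed. FPKM shares out a fixed total, so a few abundant transcripts that fall in 1 genotype can raise the values of others.

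Depth in fragments is unknown. Ratios of low FPKM values between libraries of a group were matched to steps of small whole numbers, at the shift that fitted best. That shift put 10.7% to 35.0% of ratios on steps, against a mean of at most 5.89% at random shifts. A searched shift exceeds a random mean even without real steps, so this excess does not test the fit. The fit gave relative depths within a group of 0.839 to 1.20 of replicate 1. With so few ratios on steps these depths are approximate. Between 0 and 184 genes per library were listed at exactly 0, and the lowest value above 0 was 1.39e-315, so very low FPKM can be failed estimates. A pseudocount of 1 FPKM keeps such values from setting a fold, and a fold on that scale understates the change of low genes.

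Within each stage, log2(FPKM + 1) was compared between nup1 and wild type with limma 3.58.1 in R 4.3.3, with a mean-variance trend, over genes with a mean of 1 FPKM or more in the 6 libraries. A gene passed at a Benjamini-Hochberg adjusted p under 0.01 with a fold over 2. The difference of the nup1 effect between stages was the interaction contrast over genes in both tables, at an adjusted p under 0.01, in which a scaling of a whole table cancels but a scaling between the genotypes of a stage does not. Wild type was not tested between stages, because nothing shows that the 2 tables were normalized together. Tests, groups, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. That rule takes, at each stage, the 6 largest rises and falls among genes past the threshold whose libraries do not overlap and whose higher group averages 10 FPKM or more, up to 3 members of each list past the threshold with the largest change, and TDR, EAT1, PTC1 and RbohE where listed. Other list members named below were chosen after their values were seen.

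There were 14 lists by locus: pollen wall and cuticle, tapetum regulators, tapetal cell death, respiratory burst oxidases, oxidant-removing enzymes, metallothioneins, jasmonate, meiosis, late pollen and sugar supply, photosynthesis, other floral organs, stamen identity, heat shock and housekeeping. The tables give locus identifiers without symbols, so symbols were entered in the lists from recall of published assignments, without a source to check them against at the time, and the files do not pair them. Of 164 members, 78 had their symbol on the same chromosome in the reference gene table (assembly ASM3414082v1), 81, PKS2, NP1, MST8 and TKPR1 among them, had no such symbol there and could not be checked, and 5 whose symbol lay on another chromosome were left out. Another 15 lists defined by words in gene descriptions were not applied, since no descriptions were used here. The locus mutated in nup1 is not given in the labels, so no targeted gene was checked.

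For list results the design fixed counts of members listed higher and lower on a table of called genes. Camera with a preset correlation of 0.01, the test fixed for full tables, was also run as a description, for the 5 combinations of list and stage with 5 or more members fitted. It compares a list with the other listed genes, not with the transcriptome. A Fisher test of direction was added after the values were seen. In all, 108 list p-values were computed, over 5 settings of camera, fry and the other choices fixed beforehand and 23 settings of the Fisher test.

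Alternatives were another pseudocount, other filters, median centring, quantile normalization, no trend, other thresholds, a replicate block and leaving out each library. Added after the data were seen were the Fisher test, the authors' calls as a count beside limma, leaving out 2 libraries together, median centring and quantile normalization of the stage contrast, and scaling to ACT1, which was chosen once ACT1 was seen to be lower. The authors' p or q values and a count-based test were planned only if the tables held them and were not run. On simulated data the stage 10 fit, over 3358 genes, recovered 8% of genes changed 2-fold and 50% of those changed 4-fold. The stage 11 fit, over 4992 genes, recovered 6% and 56%, with 0% false calls in both. The stage contrast, over 1405 genes, recovered 52.5% of 4-fold differences with 0.166% false calls. In the simulated stage fits only 50 genes were changed at each fold, and a call needed the adjusted p and direction without a fold minimum. Of the real fitted genes 72.9% and 72.3% passed at stages 10 and 11, so the simulated rates do not carry over to the reported calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.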

Results

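Transcripts of rice anthers were measured by RNA sequencing in wild-type plants and in the nup1 mutant, at anther stages 10 and 11, in 3 libraries of each genotype at each stage. The series title places the work in a study of an oxidative burst, the Ubisch bodies of the tapetum (the anther's innermost, nursing cell layer) and male sterility. Values are FPKM with SD over n = 3 libraries, and fold changes are differences of log2(FPKM + 1), nup1 minus wild type, with their SE and limma's adjusted p. Both tables list genes already called by the authors, so a gene outside them is not analysed here.

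The first comparison asked which genes differed in nup1 at stage 10. The largest changes among listed pollen wall and cuticle genes went both ways. PKS2 (LOC_Os07g22850), a polyketide synthase for sporopollenin, the polymer of the pollen wall, averaged 0.416 ± 0.109 FPKM in wild type and 232 ± 102 in nup1 (log2 change 7.27 ± 0.33 SE, adjusted p = 2.15e-06). RTS (LOC_Os01g70440), a tapetal gene needed for male fertility, went the other way, from 4557 ± 1985 to 15.2 ± 21.8 FPKM (log2 change -9.08 ± 0.89, adjusted p = 5.98e-05). The authors' deposited table listed 1942 genes as higher and 1511 as lower in nup1, 3453 in all.

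Of the 20 pollen wall and cuticle genes, 16 were listed, 10 higher and 6 lower. Past the limma threshold were 10 higher and 4 lower, and the counts were equal when adjusted over the list alone. NP1 (LOC_Os10g38050) rose by 5.54 ± 0.80 on the log2 scale, although its nup1 libraries spread widely, at 111 ± 96.3 FPKM. Among members chosen after their values were seen, the fatty acid hydroxylases CYP703A3 and CYP704B2 rose by 4.08 and 2.26, the acyl reductase DPW by 2.99, the acyl-CoA synthetase ACOS12 by 3.06, the transporter ABCG15 by 3.27, and TKPR1, PKS1 and STRL2 by 4.35, 1.81 and 1.39. In the opposite direction, the lipid transfer protein OsC6 went from 6991 ± 395 to 807 ± 122 FPKM, the Ubisch body protein RAFTIN1 from 2231 ± 423 to 377 ± 53.4, and CER1 changed by -1.04. As a set the list did not differ from the other listed genes (camera, adjusted p = 0.457, and adjusted p = 0.694 with an estimated correlation). The STRL2 call ended in 2 of 6 fits that left out 1 library (highest adjusted p = 0.016, without nup1 replicate 3). That of CER1 ended in 4 of 6 (highest adjusted p = 0.0231, without wild-type replicate 1) and under quantile normalization. The CYP703A3 call held in each such fit, with a change of 3.19 to 4.63.

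The tapetal cell death list had 3 of 6 members listed, and all 3 rose. The aspartic protease AP37 went from 1.44 ± 0.49 to 183 ± 56.7 FPKM (log2 change 6.21 ± 0.29), the cysteine protease CP1 rose by 2.86 ± 0.36, and AP25 rose by 2.22 ± 0.49, a call that ended without nup1 replicate 3 (adjusted p = 0.0129). PTC1 (LOC_Os09g27620), a PHD-finger regulator of tapetal development, rose from 1.12 ± 0.72 to 29.0 ± 3.6 FPKM (log2 change 3.88 ± 0.31, adjusted p = 2.8e-05). The second tapetum regulator listed, TDL1A, had a change of -0.71 ± 0.43 and did not pass.

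The late pollen and sugar supply list had 3 of 12 members listed, and all 3 fell. MST8, a monosaccharide transporter, went from 151 ± 82.3 to 0.866 ± 1.32 FPKM (log2 change -6.43 ± 0.50), and CSA, a MYB regulator of sugar partitioning, fell by 1.55 on the log2 scale. INV4, a cell-wall invertase, changed by -3.44 ± 0.84, but its wild-type level rested largely on replicate 2, without which the change was -2.27, and the call ended without nup1 replicate 2 (adjusted p = 0.0165).

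Of 34 oxidant-removing enzymes 6 were listed, 3 higher and 3 lower, and 0 passed the limma threshold, against 2449 of all 3358 fitted genes. All 6 had an unadjusted p under 0.05 and 4 an adjusted p under 0.01, so those 4 missed the threshold on the fold alone. As a set they did not differ from the other listed genes (camera, adjusted p = 0.713, and adjusted p = 0.726 with an estimated correlation). Among the respiratory burst oxidases, which make superoxide, RbohG alone was listed and rose by 1.06 ± 0.25. Its call ended in 5 of 6 fits that left out 1 library (highest adjusted p = 0.0155, without nup1 replicate 1). Median centring and quantile normalization ended it too. RbohE was not among the listed genes at either stage. The metallothionein MT2a went from 433 ± 209 to 33.7 ± 9.3 FPKM, and MT2b rose by 1.34. The MT2b call ended in 4 of 6 fits that left out 1 library (highest adjusted p = 0.0244, without wild-type replicate 1) and under median centring.

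The remaining lists had few members listed at stage 10. Among 3 listed photosynthesis genes, a Rubisco small subunit (LOC_Os12g19381) changed by -1.39 and a light-harvesting protein (LOC_Os03g39610) by 1.28. With 1 library left out, the first call ended in 2 of 6 fits (highest adjusted p = 0.0106, without nup1 replicate 3). The second ended in 4 of 6 (highest adjusted p = 0.0169, without wild-type replicate 1). The jasmonate list had 2 of 14 members listed, both higher, and AOS1 passed with a change of 1.33. That call ended in 5 of 6 fits that left out 1 library (highest adjusted p = 0.0364, without nup1 replicate 1). It also ended under median centring and when adjusted over the list alone. The meiosis list had 1 member listed, MEL2, at -0.90 and not past the threshold, and the floral organ, stamen identity, heat shock and housekeeping lists had 0. Of loci without a symbol in the lists, LOC_Os03g56890 had the largest rise (log2 change 7.97 ± 0.30) and LOC_Os03g56940 the largest fall (-9.24 ± 0.65).

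With limma, 3358 genes were fitted and 2449 passed, 1338 higher and 1111 lower, or 45.4% lower. Centring on the median of listed genes turned that share to 57.8% (962 higher, 1319 lower). Over genes all selected as changed, that step shifts the balance itself, so the true balance of the directions at stage 10 stays open. Wild-type replicate 2 differed over 2-fold from both other replicates in 8.43% of fitted genes, and 2116 genes passed without it. Without nup1 replicate 3, 881 genes were higher and 793 lower.

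**Figure D1:**
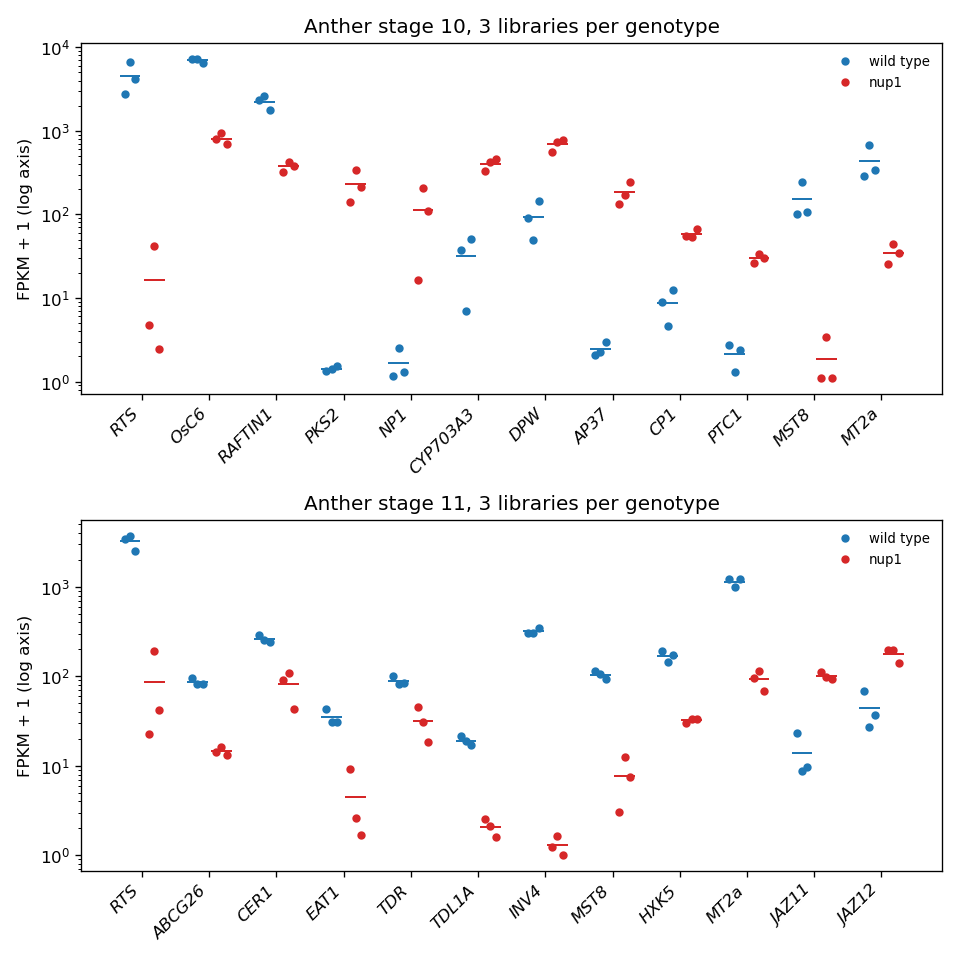
FPKM + 1 on a log axis for 12 genes at stage 10 (upper panel) and 12 at stage 11 (lower panel), with 1 point per library and a line at the mean of the 3 libraries of wild type (blue) or nup1 (red). At stage 10 RTS fell from a mean of 4557 to 15.2 FPKM while PKS2 rose from 0.416 to 232, and at stage 11 INV4 stood at 320 FPKM in wild type and 0.294 in nup1.

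The second comparison put the same question at stage 11. Of 10 tapetum regulators 4 were listed, each of them lower and past the threshold. The bHLH factor EAT1 (LOC_Os04g51070) went from 34.3 ± 7.2 to 3.50 ± 4.13 FPKM (log2 change -3.35 ± 0.58, adjusted p = 0.0013), TDL1A from 18.2 ± 2.2 to 1.08 ± 0.46 (-3.22 ± 0.23), and the bHLH factor TDR (LOC_Os02g02820) from 87.9 ± 9.7 to 30.7 ± 13.7 (-1.58 ± 0.32, adjusted p = 0.00245). TIP2, named after its value was seen, changed by -1.01. That call ended in 4 of 6 fits that left out 1 library (highest adjusted p = 0.0171, without wild-type replicate 3) and under median centring. Its sign turned under ACT1 scaling (0.04). That scaling also ended the calls of TDR (-0.40, adjusted p = 0.549) and EAT1 (-2.34, adjusted p = 0.0245), but not that of TDL1A. ACT1 was itself lower in nup1, so scaling to it raises the nup1 values of every gene. Lost calls and turned signs under it, here and below, follow in part from that step and do not test these falls. The authors' deposited table listed 2085 genes as higher and 2999 as lower, 5084 in all.

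Of the 20 pollen wall and cuticle genes 8 were listed, 1 higher and 7 lower, and 5 passed, each of them lower, as also when adjusted over the list alone. RTS went from 3229 ± 615 to 85.0 ± 93.8 FPKM (log2 change -5.81 ± 0.71), the transporter ABCG26 changed by -2.57 ± 0.16 and CER1 by -1.78 ± 0.33. RAFTIN1 and TKPR1, named after their values were seen, changed by -1.56 and -1.16, and both calls ended under median centring and when single libraries were left out (adjusted p = 0.0108 for RAFTIN1 without nup1 replicate 3 and 0.0191 for TKPR1 without wild-type replicate 3). Under ACT1 scaling the calls of CER1 (-0.59, adjusted p = 0.304), RAFTIN1 (-0.35, adjusted p = 0.439) and TKPR1 (-0.21, adjusted p = 0.676) ended, and those of RTS and ABCG26 did not. The list did not differ from the other listed genes (camera, adjusted p = 0.309, and adjusted p = 0.617 with an estimated correlation). Nup1 replicate 1 stood apart in 7.63% of fitted genes, differing over 2-fold from both other replicates, and OsC6 and CYP704B2, where it stood apart too, did not pass (adjusted p = 0.0347 and 0.133).

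The late pollen and sugar supply list again had 3 of 12 members listed, and all 3 fell. INV4 went from 320 ± 25.8 to 0.294 ± 0.322 FPKM (log2 change -7.98 ± 0.21), MST8 from 104 ± 10.1 to 6.69 ± 4.81 (-3.99 ± 0.47), and the hexokinase HXK5 from 169 ± 25.5 to 31.2 ± 2.0 (-2.39 ± 0.16).

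The jasmonate list had 6 of 14 members listed, each higher and past the threshold, also when adjusted over the list alone. The other 8 were not listed. JAZ11, JAZ12 and JAZ8, repressors of jasmonate signalling, rose by 3.01 ± 0.36, 2.10 ± 0.34 and 1.54 ± 0.28, and JAZ6 and the synthesis enzyme AOS1, named after their values were seen, rose by 1.39 and 1.23. The synthesis enzyme AOC, named likewise, rose from 88.6 ± 13.9 to 212 ± 37.7 FPKM. The AOS1 call ended without wild-type replicate 3 (adjusted p = 0.0113). The list differed from the other listed genes with a preset correlation (camera, adjusted p = 0.0103), but not with an estimated one (adjusted p = 0.617 with an estimated correlation). The Fisher test of direction, added after the values were seen, gave an adjusted p of 0.0116, and 0.146 under median centring.

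Of the 34 oxidant-removing enzymes 5 were listed, 1 higher and 4 lower. A glutathione reductase (LOC_Os10g28000) changed by -1.92 ± 0.22, and the ascorbate peroxidase APX1 by -1.08 ± 0.16. The superoxide dismutase SODCP went from 61.2 ± 4.4 to 30.1 ± 3.5 FPKM. Under quantile normalization the sign of APX1 turned (0.06). ACT1 scaling, which raises all nup1 values, turned the signs of APX1 (0.12) and SODCP (0.18) and ended the glutathione reductase call (adjusted p = 0.0352). Median centring ended the calls of APX1 (-0.64) and SODCP (-0.56), and the SODCP call also ended with quantile normalization (-0.60) and without nup1 replicate 3 (-0.92). As a set they did not differ from the other listed genes (camera, adjusted p = 0.457, and adjusted p = 0.694 with an estimated correlation). Both listed respiratory burst oxidases, RbohH and RbohC, rose, by 1.39 ± 0.20 and 1.22 ± 0.21. MT2a fell from 1141 ± 128 to 91.8 ± 23.5 FPKM, and MT-I-4b rose by 1.59. The MT-I-4b call ended in 4 of 6 fits that left out 1 library (highest adjusted p = 0.0198, without nup1 replicate 3).

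Markers of other cell types and conditions were listed in small numbers. Of 4 listed meiosis genes, 2 higher and 2 lower, MEL1, an Argonaute of germ cells, changed by -2.37 ± 0.22 and PAIR2 by -1.13, a call that ended without wild-type replicate 3 (adjusted p = 0.0188) and under median centring. The ovule gene MADS13 changed by -2.66 ± 0.46. The stamen identity gene MADS4 changed by -1.12 and a Rubisco small subunit (LOC_Os12g19381) by -1.09. Both calls ended under median centring. Both signs turned under ACT1 scaling (0.06 and 0.11), which raises all nup1 values. The Rubisco call ended in 4 of 6 fits that left out 1 library (highest adjusted p = 0.0256, without wild-type replicate 2). The photosynthesis list had 3 of 11 members listed, each a Rubisco small subunit and lower, and 0 passed when adjusted over the list alone. Of 3 listed heat shock genes HSP101 rose by 2.15 ± 0.38 and HSP70 changed by -1.74 ± 0.15. The calls of HSP70 (-0.55, adjusted p = 0.136), MADS13 (-1.62, adjusted p = 0.0127) and PAIR2 (-0.19, adjusted p = 0.689) ended under ACT1 scaling. Among the 5 housekeeping genes ACT1 alone was listed, and 4 were not. ACT1 was itself lower, from 865 ± 121 to 381 ± 94.2 FPKM (log2 change -1.21 ± 0.23). That fall did not pass under median centring (adjusted p = 0.0254), quantile normalization (adjusted p = 0.183) or without nup1 replicate 1 (-0.98). The tapetal cell death list had 2 of 6 members listed, both higher, and they did not pass (adjusted p = 0.34 for AP25 and 0.213 for CP1). Of loci without a symbol, LOC_Os02g49350 changed by -10.01 ± 0.36 and LOC_Os10g05930 by 6.29 ± 0.50.

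With limma, 4992 genes were fitted and 3610 passed, 1315 higher and 2295 lower, or 63.6% lower. The share lower was 40.0% with median centring (1880 higher, 1254 lower), 39.0% with quantile normalization and 20.6% when each library was scaled to ACT1. Every listed gene had been called changed and ACT1 was itself lower, so these steps shift the balance by themselves. They cannot show whether the excess of lower genes came from scaling. Without them, 310 genes fell and 43 rose over 8-fold.

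The third comparison asked whether the nup1 effect differed between stages, over the 1450 genes listed at both. Among genes with symbols whose difference passed, 2 genes of pollen wall synthesis had the largest. CYP703A3 had an effect of 4.08 at stage 10 and -1.47 at stage 11, where it did not pass by itself (difference -5.55 ± 0.89 SE, adjusted p = 0.000437), and TKPR1 of 4.35 and -1.16 (difference -5.51 ± 0.49, adjusted p = 1.15e-05). The effects on ABCG26, TDL1A and INV4 were negative at both stages, those on ABCG26 and TDL1A not passing at stage 10, and the differences were -1.60 ± 0.32, -2.51 ± 0.54 and -4.54 ± 1.02. Of 12 fits that left out 1 library, the INV4 difference did not pass in 7 and the TDL1A difference in 2. The highest adjusted p was 0.0134 for INV4 (without wild-type stage 10 replicate 1) and 0.0114 for TDL1A (without nup1 stage 10 replicate 3). With median centring, the differences of ABCG26 (-0.96, adjusted p = 0.0341) and TDL1A (-1.87, adjusted p = 0.0113) did not pass. For RTS, MST8 and MT2a the difference did not pass (adjusted p = 0.082, 0.0312 and 0.946).

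The authors' deposited tables listed 525 genes as higher at both stages, 726 lower at both, 119 higher then lower and 80 lower then higher, so 86.3% kept their direction where independent directions would give 50.9%. With limma 297 of 1405 fitted genes differed between stages, 74 with a more positive and 223 with a more negative effect at stage 11, and in 171 of them the sign was opposite. With median centring 143 were more positive and 138 more negative, and with quantile normalization 147 and 140. Over genes all selected as changed, these steps shift the balance themselves. They leave open whether the excess of more negative effects came from scaling. Across genes, which are not independent replicates, the effects at the 2 stages had a Pearson's r of 0.733 and a Spearman's rho of 0.710. Every gene here had been called at both stages, so these values do not describe genes called at 1 stage alone. Wild type was not tested between stages.

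**Figure D2:**
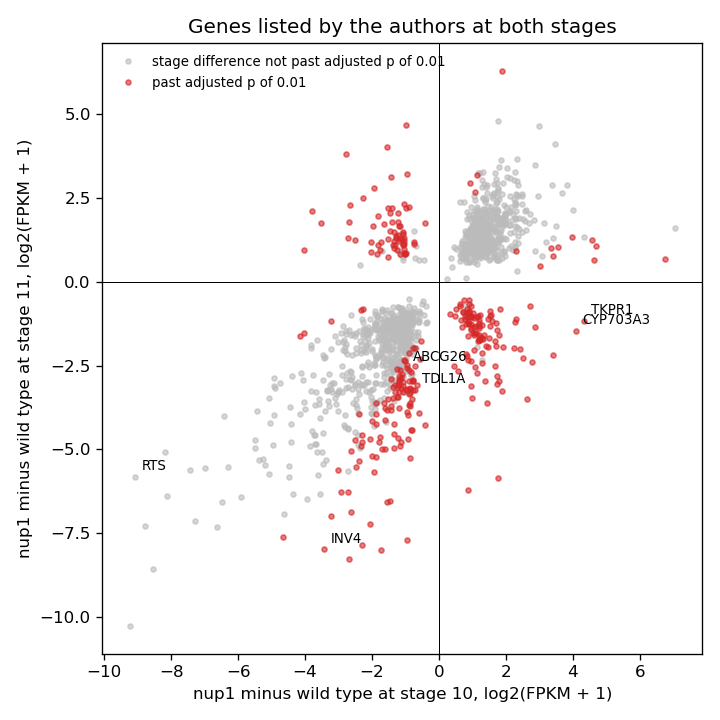
Each point is 1 of 1405 genes listed at both stages, with the log2(FPKM + 1) difference of nup1 minus wild type at stage 10 on the horizontal axis and at stage 11 on the vertical axis, and red points differed between the stages at an adjusted p under 0.01. CYP703A3 and TKPR1 lie at the lower right, at 4.08 and 4.35 on the horizontal axis and -1.47 and -1.16 on the vertical axis.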

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

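The tests of depth were chosen only after the library that each concerns was seen to stand apart. Of the 297 genes (281 with median centring) whose nup1 effect differed between stages 10 and 11 by the interaction test, 7 were list members or among the 6 largest changes of a stage, 5 with symbols and 2 without. On the log2 scale the stage 11 effect minus the stage 10 effect was -5.55 for CYP703A3, -5.51 for TKPR1, -4.54 for INV4, -2.51 for TDL1A and -1.60 for ABCG26. It was 4.40 for LOC_Os10g05930 and 5.66 for another locus without a symbol.

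At stage 10 genes were called in both directions in nup1, 1338 higher and 1111 lower, and an earlier point of development in the nup1 anthers could give such a pattern. Across the 1450 genes listed at both stages, Spearman's rho between the nup1 effect and the wild-type change from stage 10 to 11 ranged from -0.519 to 0.0869 over 6 pairings of separate wild-type libraries, so a lag cannot be told apart from an effect unrelated to timing, and the sign of rho turned with the wild-type library used. For a lag as the whole cause, a mark of under 20% was fixed beforehand. It concerns genes that change over 2-fold in wild type and whose nup1 effect goes the same way. The share was 28.3% (136 of 480), while 344 went the opposite way, the direction a lag gives. Both measures subtract the same wild-type stage 10 libraries, whose noise pushes the 2 directions to agree. The tables are also not shown to be normalized together, so this share cannot speak against a lag. In the limma fit, wild-type replicate 2 alone did not make most calls. Without it 2116 genes passed, 2046 of them among the 2449 that passed with it. The authors had selected the genes with that replicate included, so its part in their selection stays open. A direct effect of the nup1 genotype stays open and was not tested apart from timing.

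Wild-type stage 10 replicate 2 stood apart from replicates 1 and 3, with CYP703A3 at 5.9 FPKM and INV4 at 118. Its relative depth was at least 0.94 of either other library, so by that estimate it was not shallower, but 53 genes stood at exactly 0 in it, against 6 and 3 in replicates 1 and 3. Its deviations ran with the wild-type change towards stage 11, with a rho across genes of 0.547 or more in both arrangements, whereas replicates 1 and 3 set against each other gave 0.00609. A later point of development is a candidate explanation, as a hypothesis, since the tables used here hold only genes called different between the genotypes.

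Nup1 stage 11 replicate 1 stood apart from replicates 2 and 3, with CYP704B2 at 90.6 FPKM. Its relative depth was at most 1.16 times that of the others, by the approximate estimate. Genes at exactly 0 numbered 20 in it, against 96 and 184 in replicates 2 and 3, so a difference in depth stays open. Its deviations ran with the difference of nup1 stage 10 from stage 11, with a rho across genes of 0.423 or more in both arrangements, against 0.0918 for replicates 2 and 3. An earlier point of development may account for it, and a mixture of stages in the collected anthers would give the same values.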

How the results depend on the processing

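Added after the data were seen were the Fisher test of direction, ACT1 scaling, the authors' calls beside limma, leaving out 2 libraries together, and median centring and quantile normalization of the stage contrast. At a fold over 4, genes past the threshold numbered 723 at stage 10 (374 higher, 349 lower) and 912 at stage 11 (227 higher, 685 lower), since fewer genes reach that fold. At stage 11 the genes lower were 1254 with median centring, 1216 with quantile normalization and 494 with ACT1 scaling, which left 2395 in all, and the authors' calls gave 2085 higher. Leaving out 1 library gave 1674 to 2587 genes at stage 10, with 881 (without nup1 replicate 3) to 1453 higher and 793 to 1134 lower, and 2816 to 3593 at stage 11. Centring moved the median change from 0.85 to 0.66 at stage 10 and from -0.98 to -0.54 at stage 11. The difference between stages counted 227 to 364 genes with 1 library left out, 430 without the 2 libraries that stood apart, 281 with median centring and 287 with quantile normalization. For the jasmonate list at stage 11 the adjusted p was 0.617 with an estimated correlation, and the Fisher test gave 0.309 at a fold over 4, 0.146 with median centring, 0.146 with quantile normalization and 0.594 with ACT1 scaling. Over the alternatives fixed beforehand, camera and fry gave that list an adjusted p of 0.00571 to 0.617. Fry, which does not compare a list with other genes, passed where camera did not: adjusted p = 0.00208 for oxidant-removing enzymes at stage 11, and 0.0119 and 0.00188 for the pollen wall list at stages 10 and 11. Fry asks whether the genes of a list differ between genotypes, and every listed gene had been selected for that. Its values, the 0.00571 of the jasmonate list among them, are therefore no added support. Of 1361 alternatives for 87 single-gene results, 1220 kept direction and side of the threshold, 135 lost the threshold and 6 turned: APX1 with quantile normalization (0.056), and with ACT1 scaling APX1 (0.124), MADS4 (0.064), the Rubisco small subunit (0.112), SODCP (0.176) and TIP2 (0.043). ACT1 scaling moved the median change at stage 11 from -0.98 to 0.06, a shift that by itself can turn the sign of small falls. In all, 20 of the 87 lost the threshold in at least 1 fit that left out a library.

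With replicate number as a block, 2499 genes passed at stage 10, 3472 at stage 11 and 271 differed between stages, and the jasmonate list had an adjusted p of 0.006. Among single genes the block ended the stage 11 calls of TIP2 (adjusted p = 0.0102), PAIR2 (0.0128) and MT-I-4b (0.0123) and the stage difference of ABCG26 (0.0121), and no other single-gene call. The numbers are shared by label alone: deviations of same-numbered libraries correlated at 0.0382, 0.251 and 0.177 at stage 10 and -0.0931, -0.229 and 0.0825 at stage 11, and not every library correlated best with its own number, so the samples were not treated as paired.

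In the 10 splits of the 6 libraries at each stage, the real one gave 2449 and 3610 genes and the highest other 0, with 1 split as large in each; 10 splits cannot give a share under 0.05. Of 100 regroupings drawn for the stage contrast, 2 gave as many genes as the real 297, itself included, and the highest other gave 382. The genes had been selected on the real genotypes, which widens the spread within any other grouping, so these counts of splits are void as tests of chance.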

Other observations

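MT2a changed by -3.58 at stage 10 and -3.65 at stage 11, and LOC_Os03g56940 by -9.24 and -10.26, and the differences of -0.07 ± 0.50 and -1.03 ± 1.17 SE did not pass (adjusted p = 0.946 and 0.616), which does not show that the effects were equal. Genes listed at exactly 0 numbered 20, 96 and 184 in the 3 nup1 libraries of stage 11, against 0 to 4 in wild type of that stage.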
